A study of Mus musculus with 12 samples.

How the data were processed

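The study grew AKR-2B cells, a mouse fibroblast line, as colonies in soft agar, a semi-solid medium in which cells grow without attachment, with vehicle or with 25 ng/mL TGFβ. Colonies were recovered at 2, 4 and 8 days, and 12 libraries were made: 6 of miRNA and 6 of mRNA, each with 1 library per condition and day. No within-day difference therefore has a replicate check, and no p-value is given for one. Per the submitters' processing notes, edgeR 3.9 and the mouse build mm10 were used, with no role stated for either; the aligner and the miRNA counter are not given in the sources used here.

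The miRNA count table deposited by the authors holds whole reads per mature miRNA, with no normalization. A second table deposited by the authors gives RPM values, scaled to the total reads of each library, for 514 pairs of a mature miRNA and a precursor. It covers 430 mature miRNAs, which hold 99.968% of the reads of the TGFβ libraries in the count table. Its values, summed per mature miRNA, followed the unscaled counts. The mRNA data are 3 tables deposited by the authors, 1 per day, each giving a ratio (fold change) per gene with no per-sample values. Each holds 998 genes, 499 above 1 and 499 below, so genes outside them are not shown to be unchanged. The headers name no direction. The ratios were read here as TGFβ over vehicle because most listed direct TGFβ targets then lay above 1. Read the other way, every mRNA direction given here would invert. Of the 2994 ratios, 99.9% were, in lowest terms, a ratio of 2 odd whole numbers, the form taken by counts plus 0.5 with no scaling for library size. The totals of the mRNA libraries were not used here, so a difference in depth within a day stays in every ratio. In that form the larger whole number sets a lower bound on the reads behind a ratio, and 41 corresponds to at least 20 reads in 1 library. The gene symbols of the tables matched the mouse gene name and RefSeq tables used here as given for 906, 921 and 916 genes at days 2, 4 and 8 and as synonyms for 84, 69 and 77, with 8, 8 and 5 unmatched. A spreadsheet had turned 2 gene symbols into dates.

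Library totals of the miRNA counts ran from 108716 to 1387785. Scaling used trimmed mean of M-values (TMM) factors between 0.838 and 1.17 in edgeR 4.0.16 with limma 3.58.1 and R 4.3.3. Within a day, the log2 fold change was taken from CPM (counts scaled to library size) with a prior count of 2, over miRNAs with a mean of at least 10 CPM in the 2 libraries of the day. Ratios of scaled counts carry exact conditional binomial 95% intervals. A count of 0 was set to 3 counts in that library as a bound, which leaves out the counting error of the other count. A fold at this bound is therefore not a 95% limit. These intervals and bounds cover counting error only, since reads without molecular identifiers are not independent molecules. miRNAs made from several precursors or from repeats (miR-199a-3p and miR-199b-3p, let-7, miR-466, miR-467 and miR-669) share reads and are uncertain as single miRNAs.

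The only tests were edgeR quasi-likelihood tests over the 6 miRNA libraries with day as a factor plus treatment, after edgeR's expression filter, with Benjamini-Hochberg adjustment at 0.05. Days are not replicates: the 2 residual degrees of freedom hold the difference of the TGFβ response between days, so this test asks whether an effect common to the days exceeds that variation. The biological coefficient of variation was 33.4% and the prior degrees of freedom were 6.79. The fit was tested on simulated data with 309 miRNAs, 60 of them changed, in 10 runs per fold. It recovered 8.8% of 2-fold, 87.5% of 4-fold and 99.8% of 8-fold changes, with 0.3, 2.2 and 2.7 false calls per run. Every simulated miRNA had this same coefficient of variation, and each changed miRNA had the same change at all days. The real data vary in both, so these shares may be too high for them.

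Before the data were examined, 19 mRNA lists and 17 miRNA lists were fixed, together with the tests, the alternatives and the rule for named genes. For mRNA that rule took the 10 largest increases and 10 largest decreases of each day, the 10 each way with the largest mean change among genes listed at all 3 days on 1 side, and up to 4 listed members per list by absolute fold change. Ccl2, Col27a1, Ctgf, Cxcl12, Des, Hbegf, Il1rl1, Kitl, Pdgfa, Plaur, Rhob, Skil, Sphk1 and Spp1 lie outside this rule and were named after their values were seen. For miRNA, with a mean of at least 10 CPM over all libraries, it took the 10 each way with the largest mean change among those at least 1.5-fold in 1 direction at all 3 days, the 5 largest each way per day, the 10 most abundant, and list members. miRNA lists were described by the percentile of their median log2 change among 10000 random lists matched on size and mean abundance; this describes the libraries and is not a test. The lists included markers of leukocytes, epithelium and endothelium, nerve and muscle.

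Alternatives were DESeq2 1.42.0 size factors, total counts, other filters, prior counts and thresholds, DESeq2 in place of edgeR, a fit with no day term, leaving out each day, and the RPM table of the authors. Restricting the mRNA tables to ratios with a larger term of at least 41 was added after the data were seen. Other computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9. Coordinates are 1-based positions of GENCODE M21 on GRCm38, matched by gene symbol or miRNA precursor. The value of 1 listed gene is not reported here.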

Results

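The miRNA and mRNA of AKR-2B fibroblast colonies in soft agar were compared between TGFβ (25 ng/mL) and vehicle at 3 times, days 2, 4 and 8, to find the genes that TGFβ changed during colony growth. Each condition, day and kind of RNA had 1 library, so within-day differences carry counting error only and no replicate error. The miRNA libraries held 108716 reads (day 2, vehicle), 178877 (day 2, TGFβ), 232107 (day 4, vehicle), 459795 (day 4, TGFβ), 414943 (day 8, vehicle) and 1387785 (day 8, TGFβ). Of 1281 listed mature miRNAs, 664 had a read in any library and 424 to 581 in each. The 10 most abundant miRNAs of a library took 43.39% to 55.46% of its reads. By mean abundance miR-21a-5p led with 84899 CPM, followed by miR-99b-5p (78153 CPM), miR-214-3p (63455), miR-6243 (50240), miR-125b-5p (44780), let-7i-5p (39618), miR-125a-5p (31822), let-7b-5p (29725), miR-92a-3p (25395) and miR-129-5p (24424).

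Averaged over the 3 days, TGFβ raised 4 miRNAs and lowered 2 of 309 tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment). miR-21a-5p, a widely studied growth-associated miRNA whose precursor lies at 11:86584067-86584158 inside Vmp1, was higher at each day: from 6192 to 26528 reads at day 2 (scaled ratio 3.12, 95% counting interval 3.03 to 3.21), from 7839 to 47978 at day 4 (4.30, 4.19 to 4.40) and from 13696 to 143585 at day 8 (3.96, 3.89 to 4.03). Its averaged log2 change was 1.91 ± 0.20 (SE; adjusted p = 0.00169). Both arms of miR-455, at 4:63256851-63256932 inside the collagen gene Col27a1, were higher. The 5p arm went from 0 to 14 reads at day 2 (3.4-fold higher with 0 set to 3 counts), from 1 to 35 at day 4 (ratio 24.6, 4.13 to 998) and from 3 to 136 at day 8 (17.1, 5.73 to 84.0), with adjusted p = 0.0120 in edgeR. The 3p arm was 2.08 (1.34 to 3.32), 6.92 (5.52 to 8.77) and 9.06 (7.24 to 11.5) times the vehicle level, an averaged log2 change of 2.41 ± 0.49 (edgeR adjusted p = 0.0483).

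miR-224-5p, at X:72261031-72261112 inside Gabre, was 4.25 (2.56 to 7.44), 3.51 (2.61 to 4.79) and 6.65 (5.15 to 8.71) times the vehicle level at days 2, 4 and 8, with an averaged log2 change of 2.22 ± 0.40 (edgeR adjusted p = 0.0263). miR-92b-3p, at 3:89227116-89227198, was 5.14-fold, 3.61-fold and 3.94-fold lower, an averaged log2 change of -2.06 ± 0.31 (edgeR adjusted p = 0.0111). miR-1224-5p, at 16:20604452-20604536 inside Vwa5b2, went from 11 reads to 1 at day 2 (ratio 0.0662, 0.00154 to 0.455; edgeR adjusted p over the days = 0.00630). It went from 45 to 0 at day 4 and from 142 to 0 at day 8 (21.4-fold and 125-fold lower with 0 set to 3 counts). At an unadjusted p under 0.05, 89 miRNAs passed. The count rested on the days and the scaling: it was 109 without day 2, 2 without day 4, 3 without day 8, 58 with total counts (15 higher, 43 lower) and 58 with DESeq2 size factors (25 higher, 33 lower). Only miR-21a-5p and miR-1224-5p were called in all 10 alternatives.

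**Figure D1:**
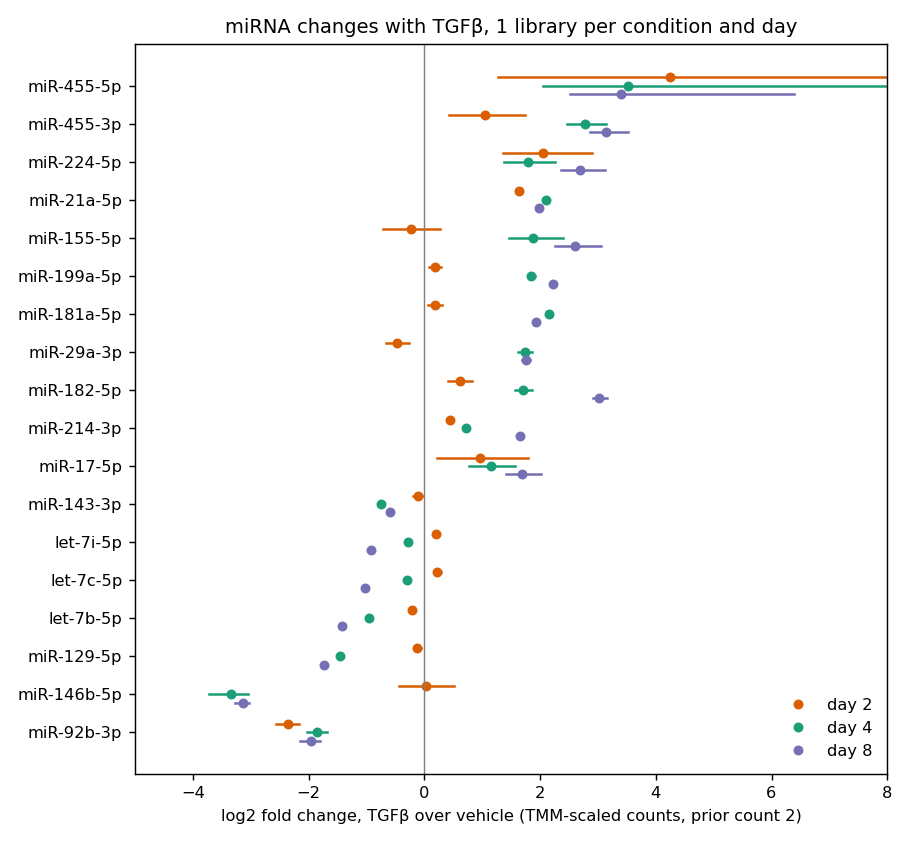
Log2 fold change of named miRNAs, TGFβ over vehicle, at days 2, 4 and 8. Points are 1 library per condition, bars are 95% counting intervals (those of miR-455-5p at days 2 and 4 run past the axis); miR-21a-5p lies at 1.64, 2.10 and 1.98, and under total-count scaling the day 2 values of miR-146b-5p, miR-181a-5p, miR-199a-5p, let-7c-5p and let-7i-5p change sign.

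Within days, miR-182-5p was 1.53, 3.28 and 8.17 (7.50 to 8.91) times the vehicle level at days 2, 4 and 8, and miR-206-3p 2.26, 6.32 and 8.41 times. Others differed more at days 4 and 8 than at day 2: miR-181a-5p was 1.14, 4.45 and 3.82 times the vehicle level, miR-199a-5p 1.13, 3.61 and 4.69 times, miR-155-5p 0.856, 3.76 and 6.23 times, and miR-29a-3p, whose family targets collagen mRNAs, 0.724, 3.33 and 3.38 times. On the lower side miR-146b-5p was at 1.03 times the vehicle level at day 2, 10.3-fold lower at day 4 and 8.87-fold lower at day 8. By contrast miR-146a-5p, in the same list of hypoxia and stress miRNAs, had log2 changes of 0.29, 1.18 and 2.26. The abundant miR-129-5p had log2 changes of -0.12, -1.46 and -1.74. miR-345-5p was 0.582 (0.116 to 2.71), 8.60 and 9.77 times the vehicle level at days 2, 4 and 8, and miR-466h-3p was at 1.36 times (0.721 to 2.68) at day 2 and 10.4-fold and 6.37-fold lower at days 4 and 8.

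At a log2 change of 1 or more, 43 miRNAs were higher and 51 lower of 362 at day 2, 79 and 65 of 366 at day 4, and 73 and 78 of 361 at day 8. Those among them whose counting interval also excluded a ratio of 1 numbered 24 and 25, 65 and 49, and 72 and 77. Scaling by total counts moved the median of all miRNAs by -0.22, -0.48 and -0.33, and the splits to 33 higher and 82 lower, 50 and 96, and 54 and 101. A change of at least 1.5-fold in 1 direction at all 3 days was seen for 24 miRNAs on the higher side and 21 on the lower side of 373. Across these 373 miRNAs, which are not independent replicates, the changes correlated with r = 0.18 between days 2 and 4, 0.18 between days 2 and 8, and 0.75 between days 4 and 8.

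**Figure D2:**
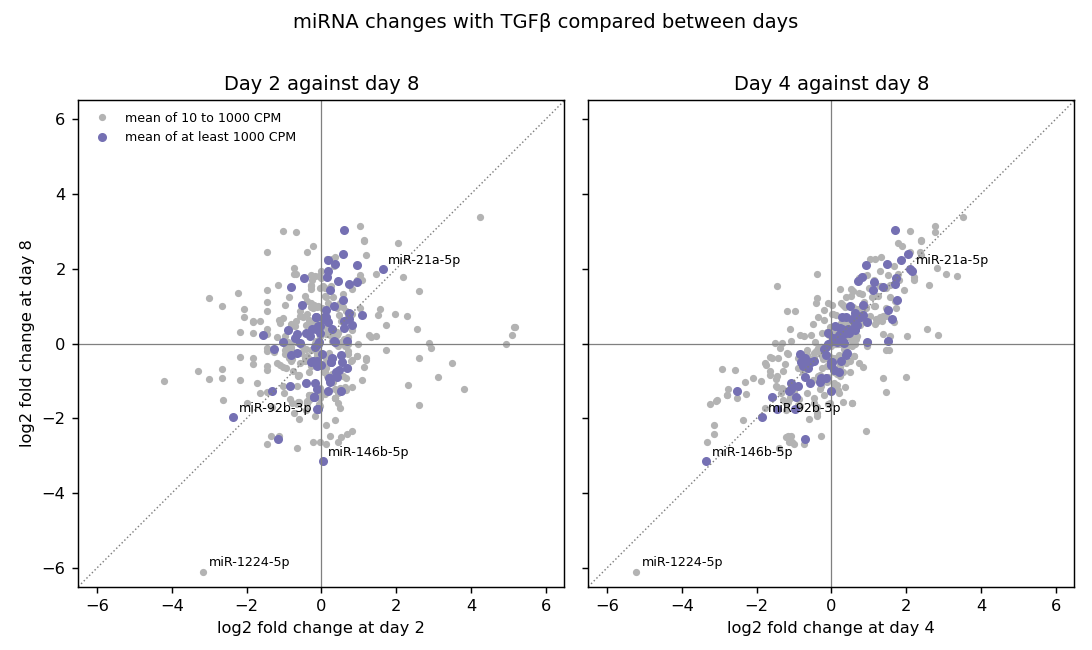
Log2 fold change of each miRNA with TGFβ at day 8 (y axis) against day 2 (left) and day 4 (right). Each point is 1 of 373 miRNAs, darker points have a mean of at least 1000 CPM, the dotted line marks equal changes, and r is 0.18 on the left and 0.75 on the right.

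Of the miRNA families, miR-17-92 and its paralogs, a cluster known for driving proliferation, were higher at days 4 and 8: 13 of 14 measured members were at least 1.5-fold higher at each, with median log2 changes of 1.77 (1.68 with a member at 0 reads set to its bound) and 1.74, above all 10000 matched random lists. The miR-181 family had medians of 1.93 (percentile 99.95) and 1.59 (99.7) at days 4 and 8, with 5 of 6 and 7 of 7 members at least 1.5-fold higher. The cluster of miR-199 and miR-214 had all 6 members at least 1.5-fold higher at days 4 and 8, with medians of 0.95 (percentile 95.2) and 1.61 (99.3); miR-214-3p was 1.36, 1.64 and 3.16 times the vehicle level at days 2, 4 and 8. let-7, which represses growth-promoting mRNAs, had 6 of 10 members at least 1.5-fold lower at day 8 (median -0.72, percentile 1.4), with let-7b-5p at -1.42, let-7c-5p at -1.03 and let-7i-5p at -0.92. Its medians were 0.22 (percentile 76.7) at day 2 and -0.13 (11.4) at day 4. The list of the Sfmbt2 cluster (miR-297, miR-466, miR-467 and miR-669) was lower at day 4, with 11 of 15 members at least 1.5-fold lower (median -1.17, percentile 0.07), and at -0.70 (4.06) at day 8. Its member miR-466i-5p was matched to a precursor at 13:17747473-17747593, outside Sfmbt2.

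The miR-23/27/24 clusters had 5 of 10 measured members at least 1.5-fold lower at day 2 (median -0.60, percentile 1.5), with medians of -0.05 and 0.09 at days 4 and 8. The miR-21 list stood at 1.64 at day 2 (98.6, the 5p arm alone; 0.68 with no filter on low counts), 1.53 at day 4 (92.4) and 1.91 at day 8 (99.5). The miR-29 family had medians of -0.18 (43.7), 1.46 (96.5) and 0.94 (93.7) at days 2, 4 and 8. Medians of the cluster of miR-143 and miR-145, which marks smooth muscle, were -0.44, -0.44 and -0.49 (percentiles 13.6, 12.9 and 16.7); miR-143-3p lay at -0.11, -0.75 and -0.60, while miR-145a-5p lay at -1.58, 0.20 and 0.23 and was below 0 at days 4 and 8 under total-count scaling. At days 2, 4 and 8 the medians were -0.28, 0.00 and -0.19 for miR-15/16, -0.53, 0.84 and 0.66 for miR-34, -0.13, 0.36 and 0.64 for miR-221 and miR-222, 0.23, 0.56 and 0.49 for miR-99, miR-100 and miR-125, and -0.17, 0.52 and 0.60 for hypoxia and stress miRNAs. Of 55 listed miRNAs of the imprinted Dlk1-Dio3 cluster, 8 were detected, with 11 reads in all libraries together.

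miR-200 miRNAs, found in epithelium, stood apart in the day 2 TGFβ library. The epithelial list had a median log2 change of 2.92 there (percentile 99.96; 2.66 with members at 0 reads set to their bounds), with 3 of 5 measured members at least 1.5-fold higher, 1 at least 1.5-fold lower (-2.65) and miR-203-3p at 0.30. It was led by miR-200b-3p with 77 reads against 1 (ratio 56.0, 9.76 to 2242) and miR-200a-3p with 26 against 0 (6.31-fold higher with 0 set to 3 counts). Measured miRNAs of blood, liver, muscle and nerve had medians above 0 at each day, 1.39 at day 2 (percentile 98.1, 4 measured; 1.04 at bounds), 1.38 at day 4 (92.7, 2 measured) and 1.67 at day 8 (95.3, 2 measured). In all, 12 of 48 list and day pairs lay below percentile 2.5 or above 97.5, 9 high and 3 low.

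Between days, 9 miRNAs were higher and 12 lower at day 8 than at day 2, averaged over treatment (edgeR, 309 tested; 88 at an unadjusted p under 0.05). DESeq2 called 52, and edgeR 58 with DESeq2 size factors and 62 with no filter. miR-140-3p, a cartilage-associated miRNA, rose by a log2 change of 2.31 ± 0.30 (edgeR adjusted p = 0.00642) and miR-99a-5p by 2.49 (0.0166), followed by miR-23b-3p (1.93), miR-181a-5p (1.93), miR-27b-3p (1.80), miR-30c-5p (1.65), miR-199a-3p (1.43), miR-378a-3p (1.22) and miR-26a-5p (1.21). A TGFβ response that differed between days is mixed into this average over treatment. For miR-181a-5p the log2 change with TGFβ was 0.19 at day 2 and 1.93 at day 8. miR-5099 fell by 2.36 ± 0.31 on the log2 scale (edgeR adjusted p = 0.00642), and miR-92b-3p, also lower with TGFβ, fell by 2.09 (0.0188). The epithelial miR-203-3p changed by -4.06 (0.0188), and miR-5119, miR-5124a, miR-6238, miR-709, miR-6538, miR-1195, miR-92b-5p, miR-690 and miR-877-3p by -5.74 to -2.43. Day 4 against day 2 gave 0 calls in edgeR, with 26 miRNAs at an unadjusted p under 0.05, and 2 in DESeq2.

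The increases in the mRNA tables were led at every day by matrix metalloproteinases, enzymes that degrade extracellular matrix. In the authors' deposited table the ratio of Mmp12 (9:7344381-7369499) was 538 at day 2, 2041 at day 4 and 3274 at day 8, and that of Mmp10 (9:7502352-7510240) was 89.5, 1205 and 862. The other genes with the largest mean increase over the 3 days were Tnnt2 (12.4, 528 and 152 in the authors' deposited table), Cdh10 (5, 93 and 535), Aldh1l1 (45, 107 and 255), Cdh6 (26.3, 181 and 182), Lrrc15 (10.3, 165 and 157), Gpr123 (11.4, 259 and 79), Megf10 (14.1, 183 and 79.8) and Acsbg1 (15.4, 77.3 and 161). The day 2 ratio of Cdh10 had a larger term below 41. Lamb3, a laminin chain, reached 4.18, 78.6 and 465 in the authors' deposited table. On the lower side, the aldehyde dehydrogenase genes Aldh1a7 (19:20692953-20727562) and Aldh1a1 had ratios of 0.00629, 0.00529 and 0.00578, and of 0.00917, 0.0141 and 0.0101, in the authors' deposited table. Spon2 (5:33198184-33218455) stood at 0.0126, 0.00411 and 0.00557, Cacna1g at 0.0462, 0.00715 and 0.00363, and the interferon-inducible Ifi27l2a at 0.0120, 0.0113 and 0.00191 in the authors' deposited table. Accn1 was 5569-fold lower at day 2 in the authors' deposited table and listed at no other day. A ratio that is an odd whole number, such as 2041, or the reciprocal of one, as for Accn1, has the form of 0 reads plus 0.5 in 1 library, and in that case its size depends on the 0.5. None of these ratios has a replicate or a scaling for depth, and the table's direction is as read here.

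The mRNA lists were counted over their listed members only and not tested. Listed direct TGFβ targets lay mostly above 1: of 32 list members, 10 were listed at any day, and 2 were above and 0 below at day 2, 9 and 1 at day 4, and 4 and 1 at day 8. The direction of the ratios was read from these targets, so the side they lie on was set by that reading and is not a result. Pmepa1 (2:173224458-173276533), a feedback inhibitor of the pathway, stood at 5.41, 22.1 and 14.2 in the authors' deposited table, and Adam12 at 5.73, 10.9 and 8.24. Hmga2 (10:120361275-120476469), a chromatin protein, stood at 8.90 and 5.51 at days 4 and 8 in the authors' deposited table, and Ctgf (10:24595442-24598683), a matricellular growth factor, at 7.90 and 8.52. At day 4 alone the authors' deposited table listed Plaur (6.97), Rhob (5.70), Skil (5.64) and Sphk1 (5.02), among others. The protease inhibitor Timp3 was the member below 1, 8.13-fold lower at day 4 and 12.8-fold lower at day 8 in the authors' deposited table.

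The few listed contractile genes, often used as markers of myofibroblasts, lay below 1 apart from Des: of 26 list members, 5 were listed at any day, and 0 were above and 3 below at day 2, 0 and 4 at day 4, and 1 and 4 at day 8. Acta2 (19:34241090-34255590), smooth muscle actin, was 17.8-fold, 12.6-fold and 16.8-fold lower in the authors' deposited table. Myosin light chain Myl9 was 31.9-fold, 26.9-fold and 36.5-fold lower in the authors' deposited table, its kinase gene Mylk (16:34745210-35002420) 18.0-fold, 58.4-fold and 69.7-fold lower, and Actg2 8.71-fold and 11.4-fold lower at days 4 and 8. Des stood at 7 on day 8 in the authors' deposited table, with a larger term below 41.

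Listed proteases and growth factors lay more often above 1 than below. Of 21 proteases and inhibitors, 4 were listed at any day, and 3 were above and 0 below at day 2, and 3 and 1 at days 4 and 8. Mmp13 (9:7272514-7283331), a collagenase, stood at 12.0, 98.3 and 64.7 in the authors' deposited table and Plau, the urokinase gene, at 3.78, 21.8 and 31.1. Of 43 growth factors and receptors, 16 were listed at any day, and 5 were above and 2 below at day 2, 10 and 0 at day 4, and 8 and 3 at day 8. Hgf stood at 10.4, 18.5 and 24.8, and Igf1 at 10.3, 26.3 and 44.3, in the authors' deposited table. Pdgfb stood at 13 and 20.1, Hbegf at 8.79 and 9.76, Pdgfa at 8.35 and 5.01, and Vegfa at 5.25 and 7.20 at days 4 and 8 in the authors' deposited table, while Kitl was 13.9-fold lower at day 8. The ratios of Igf1 at day 2 and of Pdgfb at day 4 had larger terms below 41.

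Matrix genes went both ways. Of 20 collagens, 2 were above and 2 below at day 2, 2 and 1 at day 4, and 3 and 2 at day 8: Col7a1 stood at 11.4, 18.6 and 22.6 in the authors' deposited table, Col27a1 (4:63214004-63334991) at 3.74, 6.43 and 7.45, and Col6a2 at 14.8-fold, 7.07-fold and 7.42-fold lower. Of 34 other matrix genes, 2 were above and 2 below at day 2, 3 and 3 at day 4, and 2 and 2 at day 8. The authors' deposited table gave 8.48, 20.7 and 8.95 for tenascin Tnc and 8.47, 27.7 and 15.6 for hyaluronan synthase Has2, with Mfap2 7.08-fold and 11.7-fold lower and Mfap4 7.57-fold and 19.2-fold lower at days 4 and 8.

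Listed ID and BMP-responsive genes lay below 1, with 0 of 11 above and 2, 2 and 4 below at days 2, 4 and 8. Smad9 was 10.8-fold, 7.28-fold and 10.6-fold lower in the authors' deposited table, Atoh8 (6:72206177-72235577) 7.62-fold, 14.4-fold and 92.3-fold lower, and at day 8 Id1 13.6-fold and Id3 8.32-fold lower. Interferon and chemokine genes numbered 1 above and 6 below at day 2, 3 and 4 at day 4, and 2 and 6 at day 8, of 31; with a larger term of at least 41 these were 0 and 3, 2 and 2, and 1 and 1. Ifi44 was 11-fold, 60.3-fold and 31.7-fold lower in the authors' deposited table, complement C3 30.7-fold and 24.3-fold lower at days 2 and 4, and Cxcl12 10.6-fold lower at day 2. The day 2 ratio of Ifi44 had a larger term below 41. The IL-33 receptor gene Il1rl1 stood at 10.4 and 6.04 at days 4 and 8 and Ccl2 at 6.60 at day 4 in the authors' deposited table.

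Proliferation and metabolism genes were seldom listed, which does not show them unchanged. Of 30 S phase genes, Mcm6 alone was listed (5.03 at day 4 in the authors' deposited table), and of 32 mitosis genes 0. Of 20 glycolysis genes, 2 were above 1 at day 4 and 1 at day 8, with Hk2 at 7.24 and 5.45 in the authors' deposited table. Of 17 hypoxia genes, 0, 1 and 2 were above 1 at days 2, 4 and 8, and of 26 amino acid and ATF4 genes Fgf21 alone was listed (37 at day 8 in the authors' deposited table, a larger term below 41). Of 20 cholesterol synthesis genes, Nsdhl alone was listed, at 5.18 at day 4 in the authors' deposited table.

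Cell type lists gave 0, 1 and 2 of 15 adipocyte genes above 1 at days 2, 4 and 8. Of 20 chondrocyte, bone and tendon genes, 1 was above and 1 below at day 2, 2 and 0 at day 4, and 4 and 1 at day 8, with the cartilage regulator Sox9 at 14.0 and 5.59 at days 4 and 8 and osteopontin Spp1 at 5.06 at day 8 in the authors' deposited table. Of 14 leukocyte markers, 1 was above at day 2 and 1 below at days 4 and 8. Of 15 epithelial and endothelial markers, 5 were above and 0 below at day 2, 3 and 0 at day 4, and 4 and 1 at day 8; at day 2 none had a larger term of 41 or more, with Krt8 at 33 and Cdh5 at 31 in the authors' deposited table. Of 16 nerve and muscle markers, 0 were listed at day 2, 2 were above and 1 below at day 4, and 0 and 2 at day 8.

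**Figure D3:**
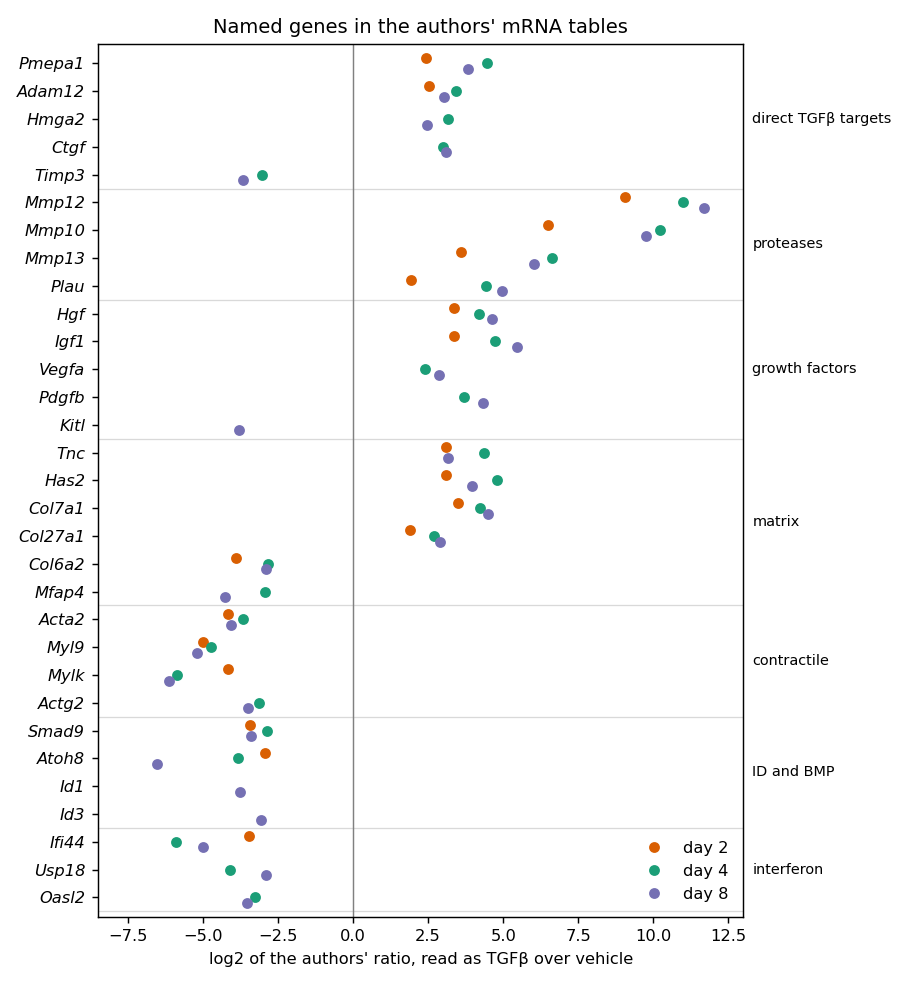
Log2 of the ratio in the authors' deposited table for named genes, grouped by list, at days 2, 4 and 8; a missing point means that the gene was not listed that day. Mmp12 has the highest ratios (538, 2041 and 3274), Mylk is at 0.0554, 0.0171 and 0.0144, and direction is TGFβ over vehicle as read here.

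Over the 3 days the tables named 2091 distinct genes. Of the 236 listed at every day, 105 lay above 1 throughout, 125 below throughout and 6 on both sides (Gdf9, Gm5833, Pgpep1l, Sh2d4a, Sult5a1 and Thsd7b, none with a larger term above 21). Days 2 and 4 shared 349 genes, 94.3% on the same side, where independent sides would give 51.0%; days 2 and 8 shared 312 (93.9% and 50.3%), and days 4 and 8 shared 478 (96.9% and 50%). Each day has its own libraries, so no library is shared between these comparisons. Of the 105 genes above 1, 95 lay further from 1 at day 4 than at day 2 and 42 further at day 8 than at day 4, with median ratios of 7, 19.8 and 15.6 in the authors' deposited table. Of the 125 below 1 these numbers were 72 and 65, with medians of 0.0667, 0.0562 and 0.0588 in the authors' deposited table. The lowest listed ratio above 1 was 3 at day 2 and 5 at day 4 in the authors' deposited table, which itself moves the listed genes above 1 further out at day 4, and depth differences between libraries stay in these ratios.

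Many ratios had small terms. The smallest listed increase was 3 at day 2 and 5 at days 4 and 8 in the authors' deposited table, and 186, 82 and 108 genes stood exactly there. With a larger term of at least 41, 89 genes were above 1 and 207 below at day 2, 212 and 181 at day 4, and 194 and 228 at day 8.

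**Figure D4:**
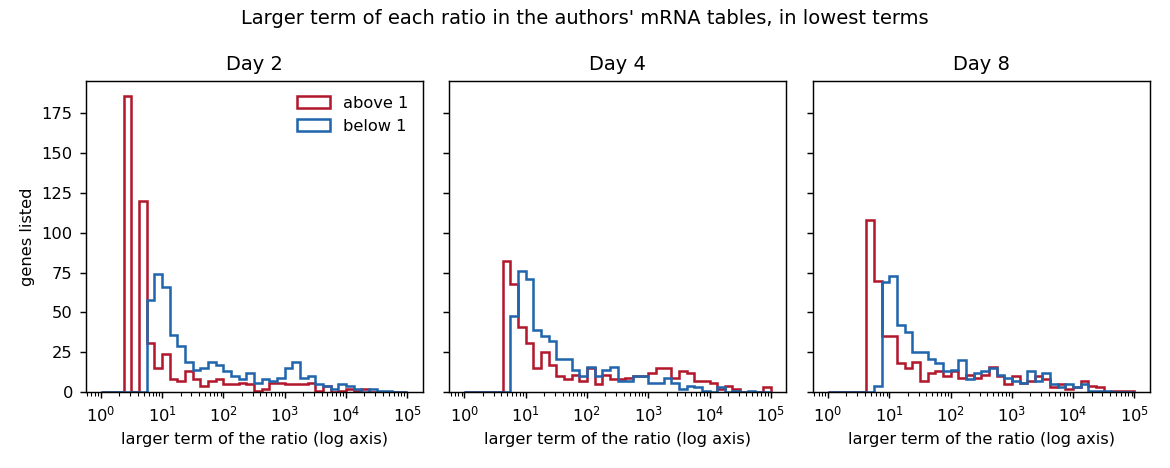
Number of genes listed (y axis) by the larger term of each ratio of the authors' deposited table in lowest terms (x axis, log scale), above and below 1, per day. The tallest bar holds the 186 genes with a ratio of 3 at day 2.

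The authors' RPM values repeat the unscaled counts. Their log2 changes differed from those of unscaled counts by at most 0.040, 0.032 and 0.046 at days 2, 4 and 8, at 20 reads or more. Closeness to the scaled counts was therefore built in and is no independent check. Pearson r was 0.993, 0.987 and 0.982 across 350, 398 and 402 miRNAs at days 2, 4 and 8. The RPM changes lay lower than those of the scaled counts by a median log2 of -0.26, -0.47 and -0.34, and 46, 74 and 48 miRNAs had the other sign. With the RPM values, 34 miRNAs were higher and 81 lower by 2-fold at day 2, 53 and 93 at day 4, and 58 and 105 at day 8.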

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

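The tests of the form of the mRNA ratios, of mRNA depth and direction, and of the day correlations as a sign of swapped labels were chosen after their results were seen; the tests of recurrence, thinning, the 4-fold miRNAs and miR-145 were not. None of the differences between days in this part was itself tested, since each condition and day has 1 library.

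Some changes ran in opposite directions at different days. miR-199b-5p had a log2 change of -1.17 at day 2 against 1.57 at day 4 and 1.57 at day 8, and miR-93-5p of -0.68 at day 2 against 1.78 and 1.87, each with counting intervals that exclude 0. Among mRNAs, 20 genes lay on opposite sides of 1 at days 2 and 4, 19 at days 2 and 8, and 15 at days 4 and 8. With a larger term of at least 41 at both days, 1 gene remained per pair, named after its values were seen: the authors' deposited table gave Gm10536 0.0120 and then 55 at days 2 and 4, Nkd2 0.101 and then 9.46 at days 2 and 8, and Tmem158 74.9 and then 0.0117 at days 4 and 8.

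The day 2 miRNA response was unlike that of days 4 and 8. Lower depth of the day 2 libraries was argued against: thinned to the day 2 totals in 100 draws, days 4 and 8 still correlated across miRNAs with a median r of 0.639 (0.586 to 0.705), against 0.18 between day 2 and either (unthinned; 0.31 and 0.38 at a mean of at least 1000 CPM, where days 4 and 8 gave 0.88). For swapped day 2 labels, the test set beforehand was near 0 and slightly on the side of a swap, with a median day 2 change of -0.11 (95% bootstrap interval -0.67 to 1.13) in the later direction over 17 miRNAs that changed 4-fold at days 4 and 8, 7 of them positive. The bootstrap drew miRNAs of the same libraries, which are not independent. Its interval therefore covers the spread among miRNAs only. If the day 2 response resembled the later ones, a swap would make the day 2 correlations negative. The lower of them was 0.176, and above 0 in every thinned draw. The draws varied only the day 4 and day 8 libraries, and the resemblance is not known. A swap therefore stays open. A difference in time under TGFβ cannot be told apart from a difference between single cultures with 1 library per condition.

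Equal small ratios filled much of the mRNA tables. In 99.9% of ratios both terms were odd, the form of unscaled counts plus 0.5, against 25.8% in simulated scaled counts. Between 5-fold and 15-fold at day 4, genes with a larger term of 20 or less recurred on the same side at day 8 in 24.1% of cases above 1 and 24.8% below, against 54.0% and 55.2% for larger terms, a gap of 29.97 points on the side where it was smaller; these listings may rest on chance reads. Unequal depth of the libraries within a day stays open: the smallest decrease exceeded the smallest increase 2.33 times at day 2 and 1.4 times at days 4 and 8, and the library totals were not used here.

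Of 5 contractile genes listed at day 8, 4 lay below 1 (not Des), while of 10 direct TGFβ targets listed at day 4, 9 lay above it (not Timp3). The direction of the ratios was read from the targets, 90% of those listed being above 1 at day 4, so the targets cannot exclude an inverted ratio, which stays open. For a depth difference alone, the prediction was that well-covered genes would lie only below 1, and 129 genes with at least 100 reads lay above it at day 8. The day 8 table lists 499 genes above 1 whatever the depth. This count therefore cannot exclude that unequal depth lowered the contractile ratios. A lower smooth muscle programme, as a hypothesis, may include miR-143 and miR-145: miR-143-3p was at -0.75 and -0.60 at days 4 and 8 but miR-145a-5p at 0.20 and 0.23, or at -0.27 and -0.11 under total-count scaling. Only miR-143-3p thus fell by the 1.5-fold predicted for both, and with 1 library per condition this leaves the hypothesis open.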

How the results depend on the processing

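The restriction of the mRNA tables to larger terms was chosen after the data were seen; the other alternatives were not. No result changed sign as a called value, and the 6 miRNAs called for TGFβ kept their direction in every alternative that tested them. Of within-day counts at 2-fold (94, 144 and 151 at days 2, 4 and 8), a minimum of 100 CPM gave 28, 61 and 76, a log2 change of 2 gave 37, 41 and 39, a 1.5-fold threshold gave 182 at day 2 and 227 at day 8, and no filter gave 212 at day 2; fewer or more miRNAs pass by construction. The 6 calls averaged over days became 58 with DESeq2 size factors, 58 with total counts, 46 with no filter and 40 with DESeq2 (48 adjusted p-values not given), and leaving out a day, which leaves 1 residual degree of freedom, gave 2 to 109, the highest without day 2; the cause was not tested. miR-224-5p was lost without day 4 or day 8 (adjusted p from 1.74e-05 to 0.193 over the alternatives), miR-455-5p likewise (1.59e-06 to 0.0997), miR-455-3p also with no day term (1.30e-05 to 0.239), and miR-92b-3p with no day term or without day 4 (1.29e-08 to 0.161). The 21 calls of day 8 against day 2 became 58 with DESeq2 size factors, 62 with no filter and 52 with DESeq2, and the 0 calls of day 4 became 2, 13 and 2; the cause was not tested. Larger terms of at least 41 left 296, 393 and 422 of 998 mRNAs and 139 of the 230 genes listed on 1 side at all days, fewer by construction. The count of miRNA lists beyond the percentiles (12) was 12 with no filter and with total counts and 11 at a minimum of 100 CPM, the alternatives run for the lists. An mRNA filter on abundance and other pseudocounts were not run, since the tables give ratios. Day 2 vehicle, with 108716 reads, limits what miRNAs of low abundance can show. The fit averaged over days is paired by day, and with no day term it gave 4 calls.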

Other observations

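The test of host genes was chosen after its result was seen; the tests of target sites and of other splits were not.

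The day 2 TGFβ library alone held 5 miRNAs with at least 10 reads and at least 10 times the level of every other library, 202 reads in all, chosen after their values were seen: miR-200b-3p (77 reads, 454 CPM), miR-10b-5p (49 reads), miR-452-5p (27), miR-200a-3p (26) and miR-204-5p (23). The other 5 libraries held 0 such miRNAs. At miRNAs with a mean of at least 1000 CPM the spread of changes with TGFβ widened with time, with a standard deviation of log2 change of 0.62 at day 2, 1.02 at day 4 and 1.15 at day 8, and across these 86 miRNAs the changes correlated with r = 0.31 between days 2 and 4, 0.38 between days 2 and 8, and 0.88 between days 4 and 8. The mRNA tables also listed 63 miRNA genes in 71 listings, 0 of them with a larger term of 41 or more, and 23 of 49 pairs with a measured mature miRNA went in the same direction, with the ratio as read here. An inverted ratio would turn each of these pairs.

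For the 6 miRNAs called for TGFβ, the 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split gave 6 calls and the highest other split 1, so 1 of the 10 splits gave as many. Only some splits placed 1 library of each day on each side, as the real split does, and these are fewer still. The others among them gave 0 calls. Splits that did not part each day mixed treatment with day and tested 343 miRNAs, not 309.

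miRNAs inside listed genes may share transcription with their hosts, as a hypothesis. Of 7 miRNAs inside 5 listed genes, 71.4% (5) went in the direction of the host on most days it was listed, too few to decide: miR-455-5p and miR-455-3p with Col27a1, miR-344b-3p with A230057D06Rik, miR-1224-5p with Vwa5b2 and miR-6538 with Rnf144a, but not the 2 arms of miR-708 with Tenm4. The counting intervals of those 2 arms included a ratio of 1. Arms of 1 precursor are not independent. By the most abundant miRNA of each host, 4 of 5 hosts and 8 of 9 pairs of host and day went the same way. An inverted mRNA ratio would turn each of these comparisons.

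Changes in let-7 and miR-21 might be seen in genes with their sites. Hmga2, above 1 at days 4 and 8, has 4 let-7 sites of 7 bases in a 3′ UTR of 3017 bases. It stood at 8.90 and 5.51 at these days in the authors' deposited table, where the let-7 median log2 changes were -0.13 and -0.72. At day 8, however, let-7 sites occurred in 9.50% of 442 searched genes above 1 and 10.5% of 447 below, percentile 27.9 among 104 other words of the same base content. With the ratio as read here, the excess that less let-7 predicts was not seen among these listed genes. miR-21 sites occurred in 7.92% above 1 and 6.71% below, percentile 79.2 among 419 words, so the deficit that more miR-21 predicts was not seen either. With an inverted ratio, the shares above and below 1 would change places, each then on the predicted side. Only listed genes were searched, at ratios of 5 or more or at least 7-fold lower at day 8. Smaller effects on targets could not be seen, so these tests do not decide. Of the listed genes, 89.1% were searched.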
